A study of Mus musculus with 9 samples.

How the data were processed

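RNA-seq and YY1 ChIP-seq were measured in splenic follicular B cells of mice with a floxed Yy1 gene: 3 mock and 3 tatcre RNA libraries, and 1 ChIP library each of naive, mock and tatcre cells. Groups and replicate numbers came from the sample titles. The sample text lists the TAT-CRE treatment for every sample, mock and naive included; the titles and the series text were followed.

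The deposited RNA files hold raw counts per gene. Per the submitters' processing notes, Trimmomatic, TopHat2, SAMtools, HTSeq and MACS2 were used with build mm10, with no versions. Per the labels' protocols, libraries came from a stranded RNA kit and a ChIP kit of the same maker. The strand setting of the counting, the annotation and the treatment of reads with several positions are not given in the sources used here. A read from an antisense or overlapping gene, or from a near-identical copy, can thus be counted differently than the symbol implies. The deposited peak files give chromosome, start and end without a score, fold or p-value, so peaks could not be ranked and the rule's peak part was replaced by totals, widths and overlaps. Whether peaks were called against a control is not given in the sources used here.

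The count files hold 48795 gene IDs, of which 48349 matched a symbol. Gene coordinates are those of RefSeq genes on GRCm38, the assembly mm10 stands for, and 91.3% of tested genes had a RefSeq row. Peak starts were written counting from 1. Because peaks lie past the last genes of GRCm38 chromosomes, the planned test of changed genes among genes with a YY1 peak is void. It had been computed on mm10 genes before the mismatch was found, and was then set aside under a condition written beforehand, that a reference not matching makes it void. Its values are not reported, and peak coordinates are printed as in the files with their build not settled. Peak lists were compared with each other in those coordinates.

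Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 15546. Libraries were scaled by TMM and tatcre was compared with mock by edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3), with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values use the TMM-scaled library sizes, and fold changes come from the fit. The biological coefficient of variation was 0.129. At this depth a count of 0 allows up to 3 counts, or 0.106 to 0.132 CPM. In data simulated on the mock means, 200 genes were changed among 15546. The test called 76, 68, 70 and 90% of genes changed by -2, -1, 1 and 2 on the log2 scale, and 5% of its calls were false. Genes removed by the filter counted as not called, 7, 7, 2 and 2 in the same order. In the data 27.1% of tested genes were called, a far larger share than was changed here, so these rates do not measure recovery in the data. No pair of libraries agreed within sampling noise: the smallest chi-square per degree of freedom between replicates was 8.07. The chi-square between mock and tatcre libraries was at least 40.3. In a principal component analysis the first axis (61.2% of variance) separated mock (-79 to -9.8) from tatcre libraries (29 to 56). The mock libraries also spread widely along this axis, so its share of variance is not that of the treatment alone. Mock 3 lay apart on the first axis and on the next (16.6%). It had the fewest genes with a count, 20420 against 21875 to 23197 in the others. Samples of the same replicate number did not clearly deviate together (correlations of deviations 0.06, -0.03 and 0.23), so no pairing was used in the main fit. With so few libraries this check does not exclude that equal numbers mark a mouse.

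Fixed before the data were examined were the test, 32 pathway lists, 9 lists of cell type markers and the rule for named genes. The rule took Yy1, Yy2 and Zfp42; the 10 largest rises and 10 largest falls among called genes with a mean log2 CPM of at least 2, no overlap between groups and a symbol that is not a clone or predicted name; the 3 called genes with the smallest adjusted p of each pathway list; and all tested immunoglobulin constant genes. Some genes that the rule names are not reported here. Other list members named in the text, cell type markers included, were chosen from the fixed lists after their values were seen. Lists with at least 5 tested members were tested with limma's camera (limma 3.58.1) at a preset correlation of 0.01 and, as an alternative, with an estimated correlation; 30 pathway lists could be tested. Counts "adjusted over the list alone" adjust the edgeR p-values within each list.

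Peak overlap needed at least 1 bp, and random overlap was taken from 1000 placements of each list within the span of all peaks of a chromosome (numpy 2.4.6, scipy 1.17.1). Shares have 95% exact binomial (Clopper-Pearson) intervals. The offset scan was devised after the lists had been seen, was tried first with wider windows and smaller offsets, and was then run with the settings given. It used steps of 250 bp in windows of at least 8 peaks and served only to ask whether a list follows gene ends; no coordinate was converted. A held-out form of it, also devised after the lists had been seen, chose each window's offset on every other peak and measured it on the rest. Alternatives were other scalings (RLE, upper quartile), DESeq2 1.42.0, limma-voom, other count filters, leaving out immunoglobulin and mitochondrial genes, a replicate block, leaving out each library, camera with an estimated correlation, fry and a reciprocal overlap of 50%. Added after seeing the data were scaling by library size alone, a mean log2 CPM of at least 2 and overlap outside clusters.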

Results

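The series profiled mouse splenic follicular B cells, the main resting B cell population of the spleen, selected on CD23 from animals whose Yy1 gene is flanked by loxP sites. Yy1 encodes the zinc finger transcription factor YY1. TAT-CRE, a cell-permeable Cre recombinase, was used to delete the gene, and a mock treatment without it served as the control. Both kinds of cells were then cultured with LPS and IL-4, which activate B cells and drive class switching, mainly to IgG1 and IgE in mice. RNA-seq gave 3 mock and 3 tatcre libraries with 22729187 to 28230727 gene counts each. YY1 ChIP-seq gave 1 peak list each for naive cells (untreated), mock cells and tatcre cells, so no ChIP difference has a replicate check. The text on the series describes spleens of 3 mice, each divided over the treatments. The labels do not say which library came from which mouse, so the p-values measure the spread between these libraries. Culture time and serum are given as 72 hours with 10% serum in the series text and as 48 hours with 20% serum in the sample text.

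To check the deletion, Yy1 RNA was examined in every library. Yy1 (ENSMUSG00000021264, chromosome 12, 108792945 to 108820148 in GRCm38) had 2655, 3018 and 2542 counts in the mock libraries and 24, 36 and 50 counts in the tatcre libraries. Its level, as library-scaled CPM, was 107 ± 5.89 CPM in mock and 1.5 ± 0.51 CPM in tatcre cells (SD, n = 3 each). Yy1 RNA thus fell 71-fold (log2 fold change -6.15, SE 0.17, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 1.7e-08). Of its related genes, Yy2 had 0 counts in all 6 libraries, which allows up to 0.132 CPM in the shallowest library. Zfp42, the other relative, had at most 11 counts in any library and was not tested. All tatcre libraries were exposed to the recombinase and no mock library was, so exposure and Yy1 loss were not separated by the design.

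The comparison of tatcre with mock cells asked which transcripts depend on YY1 during B cell activation. Of 15546 genes tested, 4215 changed, 2536 falling and 1679 rising in tatcre cells. Thus 16.3% of all tested genes fell and 10.8% rose, the shares to set beside the counts of each list below. Falls were more frequent at higher expression. Of 2554 genes of mean log2 CPM under 0, 72 fell and 107 rose. Of 2671 genes at 6 to 8, 642 fell and 292 rose, and of 777 genes at 8 and above 234 fell and 64 rose. For lists of well-expressed genes the share of all tested genes is thus a low standard for falls. Most changes were small: 535 genes were at least 2-fold lower and 390 at least 2-fold higher, and 41 were at least 8-fold lower against 15 at least 8-fold higher. The values of the 2 groups did not overlap for 44% of tested genes, where chance gives 10%. Among called genes with a mean log2 CPM of at least 2, no overlap between groups and an established symbol, the largest falls after Yy1 itself were those of Taf9b (a TATA-binding protein-associated factor), Cdk5rap2 (a centrosomal protein), Dhdh, Prepl, Dtx3 (a ubiquitin ligase of the deltex family), Ighg2b, Fam234b, Hsd17b10 (a mitochondrial dehydrogenase) and Armcx4. Taf9b went from 38.6 ± 3.21 to 0.704 ± 0.433 CPM, a 54.1-fold fall (log2 fold change -5.76, edgeR adjusted p = 1.8e-07; -6.4 without tatcre 3). Cdk5rap2 fell 26.4-fold, from 53.7 ± 0.647 to 2.03 ± 0.618 CPM, and Dhdh 20.1-fold, from 28.9 ± 3.67 to 1.43 ± 0.241 CPM. Prepl, Dtx3, Fam234b, Hsd17b10 and Armcx4 fell 12.5-, 12.1-, 10.7-, 10.3- and 9.12-fold. Under the same limits the largest rises were smaller than these falls. Cyb5d2 rose 5.22-fold, from 2.95 ± 1.15 to 15.5 ± 0.842 CPM (edgeR adjusted p = 4.9e-05), and Sulf2, an extracellular sulfatase, rose 4.27-fold to 17 ± 2.93 CPM. Thap1, a zinc finger transcription factor, rose 3.19-fold to 39.4 ± 4.9 CPM, and Dglucy, a mitochondrial D-glutamate cyclase, rose 2.97-fold to 62.7 ± 3.62 CPM. The others among the 10 largest rises under these limits were Pde7b (a cAMP phosphodiesterase), Sh3bgrl2, the long noncoding RNA Eldr, Serpine2 (a protease inhibitor), Msh5 and Tnfsf8 (the CD30 ligand), which rose 3.01- to 3.59-fold. The balance of directions moved with scaling: 60.2% of calls were falls as reported, 48.5% with upper-quartile factors (2229 rises, 2097 falls) and 42% with library size alone (2614 rises, 1894 falls), a scaling that shifts the median log2 fold change of all genes from 0.024 to 0.129. The number of rises was 998 without mock 2 and 1002 without tatcre 1.

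Because the series concerns class switch recombination, the immunoglobulin constant genes were examined next. Of the 12 tested constant genes 6 fell and none rose; adjusted over the list alone 6 fell and 1 rose. Ighg1 (ENSMUSG00000076614, chromosome 12, 113326541 to 113330523) fell 2.92-fold, from 2560 ± 167 to 875 ± 154 CPM (edgeR adjusted p = 8.6e-06). Ighg2b (ENSMUSG00000076613, chromosome 12, 113304314 to 113307933) fell 11.4-fold, from 57.6 ± 1.55 to 5.06 ± 1.08 CPM, and Ighg3 fell 2.8-fold, from 240 ± 31.4 to 85.7 ± 15.6 CPM. Ighe fell 1.56-fold, from 494 ± 48.8 to 317 ± 50.1 CPM (edgeR adjusted p = 0.0024), and Iglc1 fell 1.52-fold. Ighg2c, at 2.12 ± 0.564 CPM in mock cells, had a log2 fold change of -1.55 (SE 0.44, edgeR adjusted p = 0.024), a call that leaving out mock 2, mock 3, tatcre 1 or tatcre 2 ended. Ighm was not called at 6750 ± 684 CPM in mock and 8000 ± 908 CPM in tatcre cells (edgeR adjusted p = 0.082). It was called higher with upper-quartile factors (edgeR adjusted p = 0.0307) and with DESeq2 (adjusted p = 0.0434). The same held with the replicate number as a block (edgeR adjusted p = 0.0179), so its call depends on the fit. Ighd, Igha, Igkc, Iglc2 and Iglc3 were not called either, with edgeR adjusted p-values from 0.12 to 0.54. As a list the constant genes were called lower (camera adjusted p = 0.0153), but not when the correlation between genes was estimated (adjusted p = 0.64 with an estimated correlation). Counts over a constant gene do not separate germline from switched transcripts, and the gamma and lambda genes resemble each other closely, so their values carry that uncertainty.

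**Figure D1:**
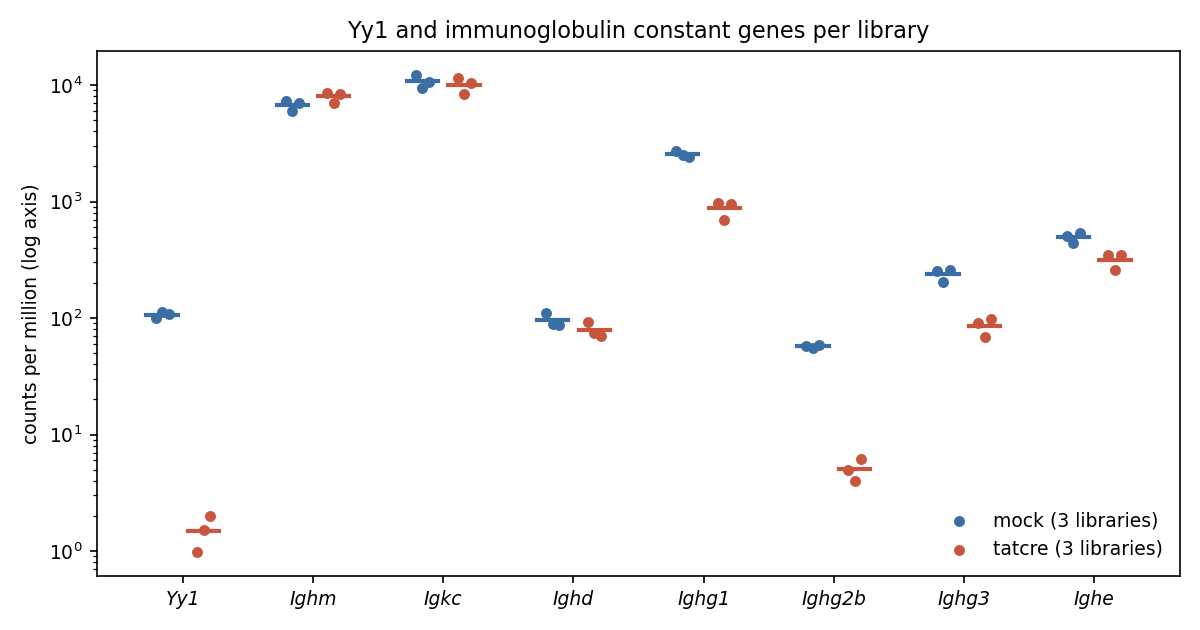
CPM (log axis) of Yy1 and 7 immunoglobulin constant genes in 3 mock (blue) and 3 tatcre (red) libraries, with each point 1 library and each line the group mean. Yy1, Ighg1, Ighg2b, Ighg3 and Ighe sit lower in every tatcre library than in every mock library, while Ighm and Igkc overlap or differ little.

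Among other genes that act in switching, 57 tested factors were examined as a list. Of these 15 fell, 6 rose and 36 were not called; adjusted over the list alone 16 fell and 7 rose, and the list was not called (camera adjusted p = 0.259; lower without the low-count filter, 0.0411). Falls included Apex1, an abasic site endonuclease (245 ± 34.8 to 145 ± 16.5 CPM), Ung, the uracil glycosylase (39.7 to 29.6 CPM), and Prkdc, the DNA-dependent kinase of end joining (73.4 to 53.2 CPM). Rises included the nuclear RNA exosome catalytic subunit Exosc10 (196 ± 11.7 to 324 ± 33.1 CPM) and the shieldin subunit Shld2 (22.9 ± 1.63 to 33.3 ± 1.89 CPM). Other subunits of these complexes fell, Exosc3 (115 to 90.3 CPM) and, at a low level, Shld1 (1.19 to 0.123 CPM), as did Mad2l2 (51 to 41.4 CPM). The damage kinase gene Atm, at 201 CPM in mock and 198 CPM in tatcre cells, was not called.

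The series title also names mitochondrial genes, and these did not move as a single block. Of 6 genes for the subunits and assembly factors of complex II of the respiratory chain 5 fell and 1 was not called, with the same 5 adjusted over the list alone. Sdhc fell 1.86-fold (47.4 ± 4.88 to 25.5 ± 3.03 CPM), Sdhd 1.47-fold and Sdha 1.39-fold, while Sdhb stood at 86.4 CPM in mock and 87.8 CPM in tatcre cells (edgeR adjusted p = 0.85). In complex III 4 of 9 fell, among them Uqcrc1 (103 ± 8.87 to 52.7 ± 2.93 CPM), Cyc1 and Uqcrc2, with the same 4 adjusted over the list alone. The fall of Uqcrc2 was lost without tatcre 1 (edgeR adjusted p = 0.0501). In complex I 7 of 36 subunits fell, led by Ndufb11, Ndufb8 and Ndufc1 at 1.84-, 1.82- and 2.3-fold, 5 rose and 24 were not called. These counts lie near the shares of all tested genes (16.3% lower, 10.8% higher). In complex IV 3 of 11 subunits fell and 8 were not called; Cox7b fell 1.66-fold and Cox8a 1.57-fold, and the fall of Cox7a2l (edgeR adjusted p = 0.041) was lost whichever library was left out. In the ATP synthase 5 of 15 genes fell, including the F1 subunit genes Atp5a1 (1210 ± 66.3 to 640 ± 33.8 CPM) and Atp5b (825 ± 32.8 to 526 ± 28.8 CPM). The counts of these 3 complexes were equal adjusted over the list alone. Camera called complex II (adjusted p = 0.00592) and complex III (adjusted p = 0.045) lower but not complex I, complex IV or the ATP synthase (adjusted p = 0.272, 0.201 and 0.102). The ATP synthase list was lower with fry (adjusted p = 0.0143), without tatcre 1 and without the low-count filter, and complex I without that filter (camera adjusted p = 0.0414). Neither called list held with an estimated correlation (adjusted p = 0.42 with an estimated correlation for each). Complex III was lost with RLE and upper-quartile factors (camera adjusted p = 0.05002 and 0.07998) and with a replicate block (camera adjusted p = 0.05984). It was also lost without mock 2, tatcre 2 or tatcre 3, and without genes of mean log2 CPM under 2 (camera adjusted p = 0.221). The 13 mitochondrially encoded mRNAs are listed at 0 in every library, as are all 37 genes of that genome, so they say nothing about it.

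Other mitochondrial groups held strong single falls, and camera called the fatty acid oxidation and TCA cycle lists lower. Among 18 fatty acid oxidation genes 8 fell, 1 rose and 9 were not called, the same adjusted over the list alone. Eci1, an enoyl-CoA isomerase, fell 24-fold (14.9 ± 0.994 to 0.612 ± 0.21 CPM), Echs1 3.79-fold and Decr1 2.28-fold, while Acadvl rose from 22.6 to 29.6 CPM. The list was lower (camera adjusted p = 0.00909; adjusted p = 0.42 with an estimated correlation), though not with genes of mean log2 CPM under 2 left out, a choice made after seeing the data (camera adjusted p = 0.245). In the TCA cycle 6 of 19 fell, with the succinyl-CoA ligase subunits Suclg2 (2.82-fold) and Sucla2 (1.78-fold) and the pyruvate dehydrogenase component Pdhx (1.5-fold) leading, the same 6 adjusted over the list alone. That list was lower (camera adjusted p = 0.0409, with an estimated correlation adjusted p = 0.44). It was lost with RLE and upper-quartile factors (camera adjusted p = 0.05002 and 0.08975), with a replicate block (camera adjusted p = 0.05394) and without mock 2 or tatcre 2. Leaving out genes of mean log2 CPM under 2 also ended the call (camera adjusted p = 0.268). Of 77 mitochondrial ribosome genes 19 fell and 8 rose (21 and 9 adjusted over the list alone); Mrps18b fell 2.8-fold and Mrpl42 1.99-fold, and Mrps15 rose 1.57-fold. Of 27 import genes 6 fell and 1 rose, the same adjusted over the list alone; Grpel1, Dnajc15 and Timm22 fell 1.87-, 1.61- and 1.55-fold. Among 23 genes of mitochondrial DNA maintenance and transcription 3 fell and 2 rose (2 and 2 adjusted over the list alone), including the coactivator Ppargc1b, which fell 4.38-fold, Slirp, which fell 1.45-fold, and Ssbp1, which rose 1.3-fold. Among 23 genes of mitochondrial dynamics and quality control 5 fell and 4 rose, the same adjusted over the list alone, with Bnip3l and Afg3l1 falling 1.73- and 1.44-fold and the fusion GTPase Mfn1 rising 1.45-fold. Camera called none of these last 4 lists (adjusted p from 0.158 to 0.91), though the import list was lower without mock 1 (camera adjusted p = 0.0327), and import and mitochondrial ribosome lists without the low-count filter.

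**Figure D2:**
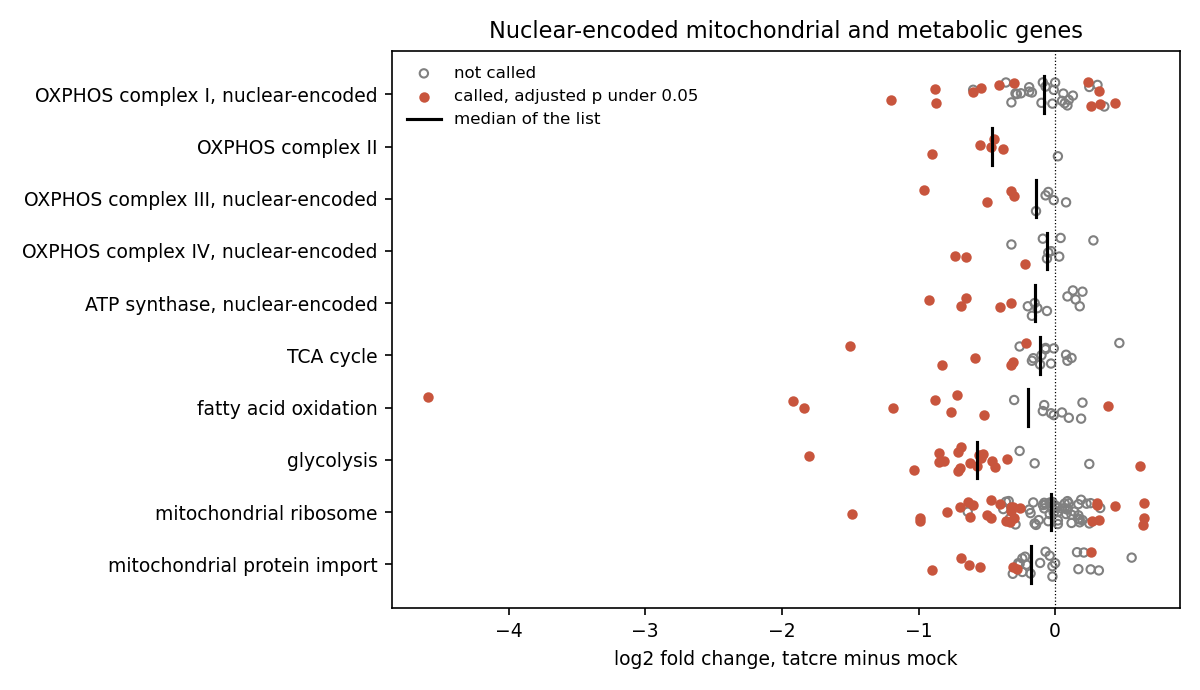
Log2 fold change (tatcre minus mock) of each tested gene in 10 fixed lists, with filled points called at an adjusted p under 0.05, open points not called and the bar at the list's median. Glycolysis has the lowest median (-0.57), followed by complex II (-0.46), and Eci1 lies farthest left at -4.59.

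Most tested genes of glycolysis and of cholesterol synthesis fell. Of 21 glycolysis genes 17 fell, 1 rose and 3 were not called (18 and 1 adjusted over the list alone). Pfkp, a phosphofructokinase, fell 1.64-fold (340 ± 14.3 to 208 ± 6.03 CPM), the hexokinase gene Hk2 went from 87.1 to 53.5 CPM, the glucose transporter gene Slc2a1 from 64.6 to 39.6 CPM and the pyruvate kinase gene Pkm from 2330 to 1700 CPM, all called lower, while Pfkm rose (7.85 to 12.1 CPM). Eno1 and Gapdh fell 3.49- and 2.05-fold, but these genes have near-identical copies in the genome and their counts are uncertain. Of 23 cholesterol synthesis genes 17 fell and 6 were not called (18 falls adjusted over the list alone). Lss, Nsdhl and Sqle, enzymes of the sterol branch, fell 1.83-, 1.77- and 1.64-fold. Camera called both lists lower, at adjusted p = 1.55e-07 for glycolysis and 5e-08 for cholesterol synthesis. With an estimated correlation between genes neither held (adjusted p = 0.32 and 0.3 with an estimated correlation).

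B cell activation and identity genes were mostly lower in tatcre cells. In the list of activation and IL-4 or LPS response genes 19 of 37 fell and 2 rose (23 and 2 adjusted over the list alone). Egr2 fell 2.38-fold (95.7 ± 5.72 to 40.1 ± 5.28 CPM), the cytokine gene Lta fell 2.24-fold, and Myc fell from 304 ± 31.9 to 179 ± 19.4 CPM. Bcl2a1d, which has near-identical neighbours, fell 2.39-fold. Il10 rose (log2 fold change 0.82, SE 0.18, edgeR adjusted p = 0.0067), as did Socs3, and Cd69, Cd80 and Il6 were not called. Of 24 B cell identity genes 13 fell and 11 were not called, the same adjusted over the list alone. Cd72 (75.4 ± 6.41 to 33.2 ± 2.49 CPM), the kinase gene Blk (16.4 ± 2.31 to 5.24 ± 0.432 CPM) and Fcer2a, which encodes the CD23 used for selection (1150 ± 18.1 to 753 ± 28.2 CPM), fell, as did Pax5 with a log2 fold change of -0.34. Of 19 plasma cell genes 8 fell and 11 were not called (9 falls adjusted over the list alone); Edem1, Slamf7 and Irf4 fell 1.47-, 1.54- and 1.35-fold, while the plasma cell regulators Prdm1 and Xbp1 were not called (log2 fold changes -0.08 and -0.07). Camera adjusted p-values were 0.000347 for activation, 9.45e-05 for identity and 0.00691 for the plasma cell list. None held with an estimated correlation (adjusted p = 0.41, 0.35 and 0.42 with an estimated correlation), and the plasma cell list was also lost without genes of mean log2 CPM under 2 (camera adjusted p = 0.0838).

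Stress response genes moved in opposite directions by list. Of 34 genes of the unfolded protein and integrated stress responses 17 fell and 17 were not called (18 falls adjusted over the list alone). Atf4, the central transcription factor of the integrated stress response, fell 2.08-fold (475 ± 15.2 to 229 ± 24 CPM), Atf3 2.46-fold and Herpud1 1.66-fold. The chaperone Hspa5 was not called (log2 fold change -0.08, edgeR adjusted p = 0.43). By contrast 15 of 30 p53 targets rose, 3 fell and 12 were not called (16 and 3 adjusted over the list alone). Cdkn1a, which encodes the cell cycle inhibitor p21, rose 2.35-fold (20.2 ± 1.54 to 47.3 ± 5.42 CPM), Zmat3 2-fold and Psrc1 1.92-fold, and the pro-apoptotic Bax and Bbc3 were not called (edgeR adjusted p = 0.35 and 0.11). Camera called the stress list lower (adjusted p = 1.08e-05; adjusted p = 0.42 with an estimated correlation) and the p53 list higher (adjusted p = 0.00405; adjusted p = 0.32 with an estimated correlation). Of 26 apoptosis regulators 7 rose and 4 fell (9 and 5 adjusted over the list alone), with Bcl2l2 and the pro-apoptotic Bcl2l11 rising 1.62- and 1.61-fold. That list was not called (camera adjusted p = 0.579).

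Chromatin and cell cycle lists held calls in both directions. Of 19 cohesin, CTCF and condensin genes 4 rose and 1 fell (5 and 1 adjusted over the list alone); the cohesin genes Rad21 and Smc3 rose 1.67- and 1.26-fold and the condensin gene Ncapd3 1.21-fold (lost without mock 2 or tatcre 1), and Ctcf was not called (320 and 350 CPM). The list was higher (camera adjusted p = 0.0276, with an estimated correlation adjusted p = 0.64). Leaving out mock 1, mock 2 or tatcre 2 or the low-count filter ended the call, as did a replicate block (camera adjusted p = 0.05712). Among 34 Polycomb and INO80 genes, whose complexes bind YY1 or act with it, 9 fell and 6 rose, the same adjusted over the list alone; Sfmbt2, L3mbtl2 and Bmi1 fell 4.55-, 2.67- and 1.8-fold, and the list was not called (camera adjusted p = 0.0529), though it was lower with fry (adjusted p = 0.00656), without the low-count filter, and without mock 1, tatcre 1 or tatcre 3. Of 40 replication genes 9 fell and 2 rose (12 and 2 adjusted over the list alone), with Mcm5, Rfc2 and Uhrf1 falling 2-, 1.32- and 1.28-fold. That list was not called (camera adjusted p = 0.0505), though it was lower with limma-voom (camera adjusted p = 0.0374), without the low-count filter, and without mock 1, mock 3, tatcre 1 or tatcre 3. Of 31 mitotic genes 5 fell and 2 rose, the same adjusted over the list alone; Birc5 and Aurka fell 1.46- and 1.28-fold, Cenpf rose 1.31-fold, and Mki67 was not called (camera adjusted p = 0.606).

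Lists of RNA and protein handling were examined next. Of 32 ribosome biogenesis genes 14 fell and 2 rose (16 and 2 adjusted over the list alone), with Nob1 and Bop1 falling 1.76- and 1.78-fold and Utp20 rising 2.22-fold. Of 36 proteasome genes 12 fell and 1 rose, the same adjusted over the list alone; Psmc3, Psmd11 and Psmb9 fell 1.92-, 1.67- and 1.42-fold. Camera called both lower (adjusted p = 0.00592 and 0.00883), neither with an estimated correlation (adjusted p = 0.75 with an estimated correlation for each), and the proteasome list was lost without tatcre 2 and without genes of mean log2 CPM under 2 (camera adjusted p = 0.119). The test fry called neither list (adjusted p = 0.171 and 0.0811). Of 34 splicing genes 8 fell (7 adjusted over the list alone), including Prpf8, Snrpa1 and Srsf7 at 1.6-, 1.38- and 1.37-fold. That list was called lower (camera adjusted p = 0.04996, with an estimated correlation adjusted p = 0.75). The call ended under both other planned scalings, with fry, with a replicate block, and without mock 2, tatcre 1 or tatcre 2. It also ended without genes of mean log2 CPM under 2 (camera adjusted p = 0.271). Of 77 cytosolic ribosome genes 6 rose and 7 fell (5 and 6 adjusted over the list alone; camera adjusted p = 0.91). Rpl15, Rpl5 and Rpl31 rose 1.8-, 1.65- and 1.58-fold, and these genes share reads with pseudogenes, so the values are uncertain. Of 28 interferon-stimulated genes 8 fell and 2 rose, the same adjusted over the list alone, with Isg15 and Ifih1 falling 1.6- and 1.49-fold and Bst2 rising 1.66-fold. That list was not called (camera adjusted p = 0.108), though it was lower without mock 2 or tatcre 1 and without the low-count filter.

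**Figure D3:**
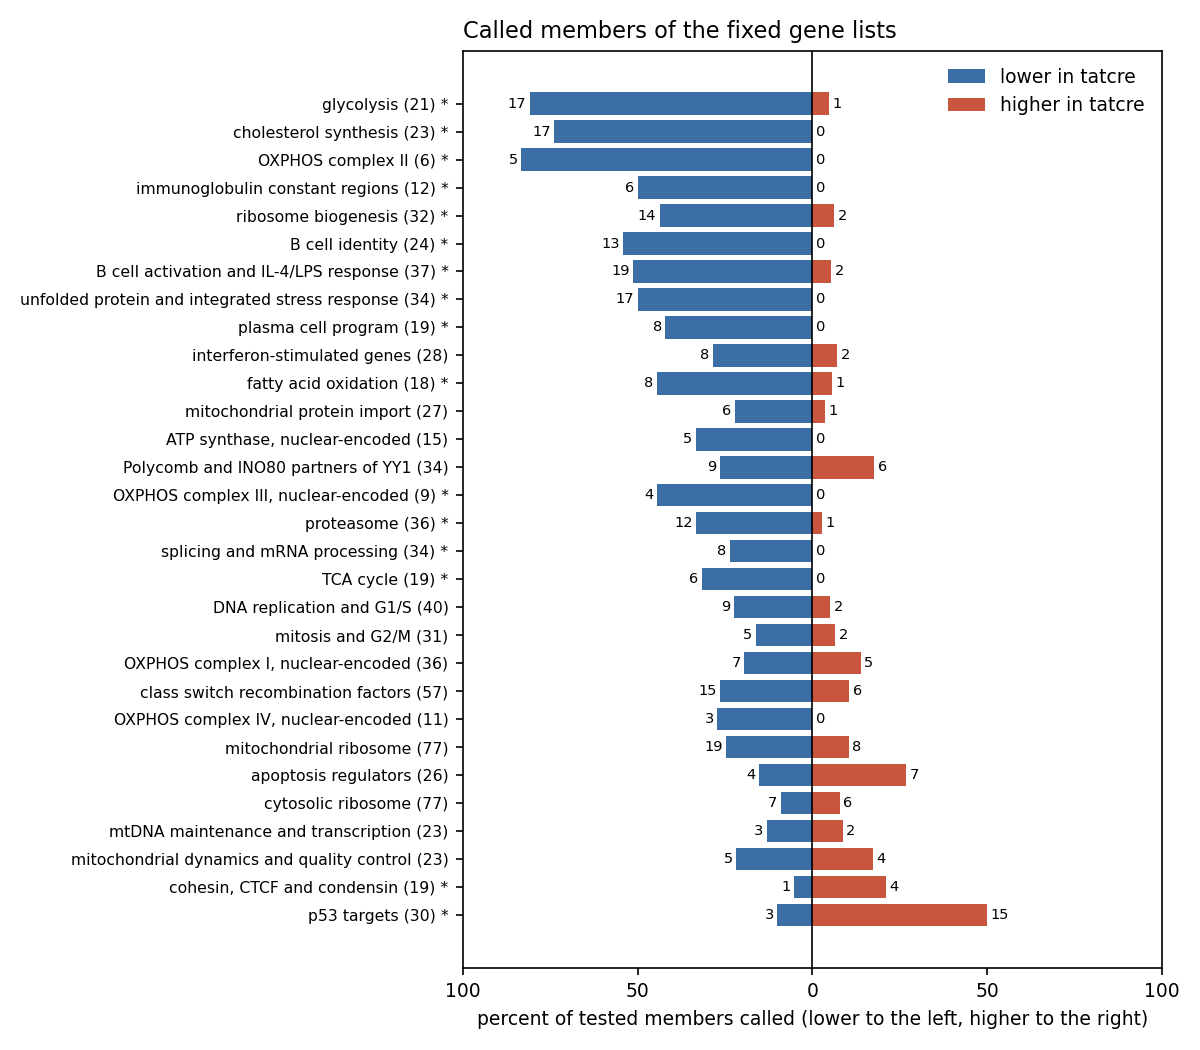
Percent of tested members of each fixed list called lower (blue, left) or higher (red, right) in tatcre than in mock cells, with the number of genes at each bar, tested members in brackets and an asterisk where camera called the list. Glycolysis (17 of 21) and cholesterol synthesis (17 of 23) fell most widely among lists of more than 10 genes, and p53 targets (15 of 30) rose most widely.

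Markers of other spleen cells were examined because the cells were selected on 1 surface protein. The CD3 genes, Lyz2, C1qa and the globin genes did not pass the count filter. Of 16 T cell markers 5 were tested; Thy1 and Lck fell (213 to 109 and 17 to 10.3 CPM) and Lef1 rose, the same adjusted over the list alone. Of 15 macrophage and monocyte markers 6 were tested; Cd68 and Hmox1 fell, and Mrc1 and Vcam1 rose at levels below 3 CPM, the same adjusted over the list alone. In dendritic cell markers Batf3 and Flt3 fell and Bst2 rose, and in 8 stromal and endothelial markers Col1a1 rose (0.418 to 1.89 CPM) and Pecam1 fell, the same adjusted over each list alone. The NK marker Gzmb and the mast cell marker Kit were tested and neither was called, and no erythroid or platelet marker was tested. Of 10 marginal zone markers Cr2, Dtx1 and Mzb1 fell (4 falls and 1 rise adjusted over the list alone), and of 9 follicular markers 4 fell, among them Fcer2a, Cr2 and Ccr7, with the same 4 adjusted over the list alone. Camera called none of the 6 marker lists it tested, the lowest adjusted p being 0.0672 for the follicular markers. The follicular list was lower with fry (adjusted p = 0.0036), which called no other marker list.

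YY1 binding was compared as peak lists, to see where YY1 sat in naive and activated cells and what remained after deletion. The naive list held 2349 peaks, the mock list 999 and the tatcre list 2069. Many mock sites were shared with naive cells: 804 of 999 mock peaks (80.5%, 95% exact binomial interval 77.9 to 82.9) overlapped a naive peak by at least 1 bp, where 1000 random placements gave at most 4. With a reciprocal overlap of 50% the share was 40.8%. Of the naive peaks 791 (33.7%, interval 31.8 to 35.6; 17.4% with a reciprocal overlap of 50%) overlapped a mock peak. The tatcre list was a nearly separate set, with 36 mock peaks (3.6%, interval 2.54 to 4.95) overlapping it and 29 tatcre peaks (1.4%, interval 0.941 to 2.01) overlapping the mock list. Tatcre peaks were also uniform in width, 57.7% of them at the minimum of 153 bp. Of mock peaks 10.5% were at their minimum of 104 bp, and of naive peaks 14% at theirs of 163 bp. Median widths were 153 bp for tatcre, 163 bp for mock and 274 bp for naive peaks, so tatcre peaks were little narrower than mock peaks. Depth, control library and calling threshold of each list are not given in the sources used here, so the numbers of peaks do not measure how much YY1 was bound, and intervals cover counting error only.

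Of the 36 mock peaks shared with the tatcre list, 15 lay outside clusters of peaks. In the files' own coordinates, the interval on chromosome 9 from 2999919 to 3038349 held 11 naive, 17 mock and 13 tatcre peaks, and the interval on chromosome 2 from 98502304 to 98507563 held 3, 4 and 4. Outside clusters of at least 4 peaks of a list within 50 kb, 15 of 958 mock peaks (1.57%) overlapped a tatcre peak and 770 (80.4%) a naive peak.

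The submitters name mm10 as the genome build, but peak positions run beyond its last genes. On chromosome 7 the last mock peak ends at 152336284, which is 7.01 Mb past the last gene annotated there in GRCm38, and the last naive and tatcre peaks end 5.51 and 6.21 Mb past it. Genes near peaks were therefore not assigned, and no result on genes with a YY1 peak is given. To learn whether each list followed genes at all, peaks were slid along each 10 Mb window by up to 8 Mb. In 94 of 120 windows the best offset placed at least 50% of the naive peaks within 500 bp of an end of a protein-coding gene, and in 88 of these it exceeded 1 kb. At the offsets of those 88 windows 69.4% of naive peaks (chosen for this) and 70.9% of mock peaks (interval 67.2 to 74.4) lay at a gene end, against 4.66% and 3.89% with no offset. The mock value is not independent of the choice of windows, since mock peaks overlap the naive list. With offsets chosen on every other naive peak of 120 windows, 47.1% of the remaining 871 lay at a gene end (interval 43.7 to 50.4), beside a mean of 2.4% over other offsets. The same procedure on the tatcre list's own windows gave 2.85% (interval 1.72 to 4.41), beside 1.82%. Of 851 tatcre peaks in the 88 windows 3.06% lay at a gene end at the naive offsets (interval 2.01 to 4.44), beside a mean of 2.19% over other offsets.

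**Figure D4:**
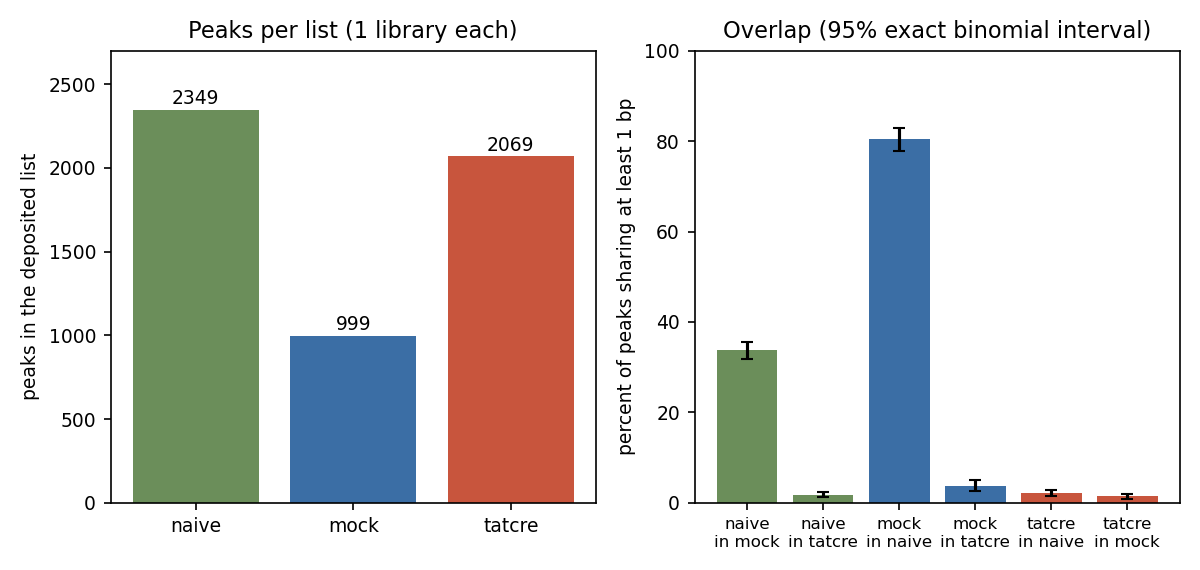
Left, number of YY1 peaks in the naive, mock and tatcre lists (1 library each); right, percent of peaks of each list that share at least 1 bp with another list, with 95% exact binomial intervals. At this overlap 80.5% of mock peaks lie in the naive list (40.8% with a reciprocal overlap of 50%), and every overlap that involves the tatcre list is below 4%.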

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

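The tests with offsets, those outside clusters and the one without mock 3 were chosen after the result was seen; the others were set before.

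The mock list held 9 peaks on chromosome Y, between 2779748 and 2891993 in the file's coordinates, while the naive and tatcre lists held 0. Of these peaks 7 lay in a cluster of 34.4 kb. All 9 were kept among the 999 mock peaks of the overlap shares. Whether they mark YY1 binding was not tested. The Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y had 0 counts in all 6 RNA libraries.

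The count of 4215 changed genes came from the real grouping, and the highest of the other 9 ways to split the 6 libraries into groups of 3 gave 0 at the same threshold by edgeR. Only 1 of 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05. Each other split mixes mock and tatcre libraries within both groups. A large difference between the conditions then adds to the spread within groups, so the 0 is no separate evidence.

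Of naive and mock peaks 11.2 and 10.1% lay within 1 kb of a gene end of mm10, which is 2.95 and 2.77 times random placement. At the offsets found in the naive list, 70.9% of mock peaks lay within 500 bp of a gene end against 3.89% with no offset, but this value decides nothing alone, because the offsets were chosen on naive peaks that mock peaks overlap. With offsets chosen on every other naive peak, 47.1% of the naive peaks held out lay at a gene end, against 2.4% over other offsets. Of 111 mock peaks that overlap no naive peak 46.8% did at the naive offsets, against 2.33%. With no offset the shares were 8.15% of these held-out naive peaks and 0.901% of these mock peaks. These shares argue against mm10 coordinates for the naive and mock lists. Peak ends past the last GRCm38 genes argue against them for all 3 lists. The tatcre list held 8 such peaks on 3 chromosomes, up to 6.21 Mb past the last gene of chromosome 7. Which other build holds was not tested.

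The tatcre list shared 3.6% of mock peaks. At the offsets of the naive list 3.06% of tatcre peaks lay at a gene end, close to the 2.19% at other offsets, so calls spread over background may make up most of that list; the same test without offsets (1.1 times random) decides nothing, because positions in all 3 lists run past the last genes of mm10 chromosomes. The 36 mock peaks that overlap it had a median width of 326 bp, above all random sets of as many mock peaks (percentile 100), and the 15 outside clusters stood at percentile 98.6. Leftover YY1 at the strongest sites predicts such widths. An overlap of at least 1 bp also favours wide peaks, and the random sets were not weighted by width, so the widths cannot decide. The strength of sites was not measured. Wide regions that give peaks in any library stay open, because clusters on chromosomes 2 and 9 hold much of the overlap. With 1 library per condition, loss of YY1 and a weak immunoprecipitation were not separated.

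Low-expressed genes leaned higher in tatcre cells: 2554 genes of mean log2 CPM under 0 had a median log2 fold change of 0.62, with 107 called higher and 72 lower, against a median of -0.11 for the 777 genes of 8 and above. Their summed level overlapped between groups, 1035 to 1727 CPM in mock and 1634 to 2302 CPM in tatcre libraries. Mock 3, which had the fewest detected genes, is not the whole cause, as the median without it was 0.41. Background reads over silent genes cannot be told apart from a change in these genes: olfactory and vomeronasal receptor genes summed to 15.4 ± 2.75 CPM in mock and 20.2 ± 6.43 CPM in tatcre libraries (SD, n = 3 each), a ratio of 1.31 with an SE of 0.28. The overlap of the libraries meets the bound written beforehand against background reads, but the ratio lies within its spread of the bound for them, so the test is not taken to decide.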

How the results depend on the processing

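Library size alone, the mean log2 CPM of at least 2 and overlap outside clusters were chosen after seeing the data. Yy1 RNA was lower under all 16 alternatives run on it (log2 fold change -6.43 to -5.93). Changed genes numbered 925 (390 higher, 535 lower) with a fold threshold of 2, which keeps fewer genes by construction, and library size alone gave 2614 higher genes. Leaving out 1 library gave 2958 to 3963 changed genes, 998 to 1681 of them higher and 1960 to 2391 lower, with fewer samples. With the replicate number as a block, 3421 genes were called, and 79.2% of the 4215 were shared. The same numbers deviate with correlations of 0.06, -0.03 and 0.23, and not every sample correlates best with its own number. With so few libraries this check cannot settle whether equal numbers mark a mouse. Ighm was called with the block (edgeR adjusted p = 0.0179), and Cox7a2l and Ncapd3 were not (edgeR adjusted p = 0.0892 and 0.0564). The complex III, TCA cycle, cohesin and splicing lists lost their call with it (camera adjusted p = 0.05984, 0.05394, 0.05712 and 0.05678). The interferon-stimulated list gained one (camera adjusted p = 0.04754). No call shared with these alternatives changed sign. Of 30 lists 16 were called; with an estimated correlation 0 were, with fry 15, with the block 13, with a mean log2 CPM of at least 2 there were 10, and leaving out 1 library gave 11 to 19. Camera compares a list with all other tested genes, so a call of lower is relative to them. Genes of mean log2 CPM under 0 and of 0 to 2 had median log2 fold changes of 0.62 and 0.22. Whether this lean accounts for the calls lost at a mean log2 CPM of at least 2 was not tested, nor were other causes. Of 118 other named genes 4 lost their call under some alternative (Cox7a2l, Uqcrc2, Ncapd3 and Ighg2c) and 2 gained one (Ighm and Ighd). A reciprocal overlap of 50%, stricter by construction, gave 40.8% of mock in naive, 17.4% of naive in mock, 2.1% of mock in tatcre, 1.19% of naive in tatcre and 1.35% of tatcre in naive peaks. Outside clusters, the last 3 were 1.57, 1.17 and 1.27%, and 0.731% of tatcre peaks overlapped mock peaks. Peaks above the median score could not be taken, as the files give no score. The test of genes with a YY1 peak and its alternatives are void by build and left out. Overlap of peaks of at least median width and peaks at either gene end, also chosen after seeing the data, were computed and dropped: in the tatcre list the median is the minimum width, and the other is void by build. In the simulation 68 and 70% of genes changed by -1 and 1 on the log2 scale were recovered. It held far fewer changed genes than the data, so these rates do not carry over. The effect of depth itself was not tested.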

Other observations

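The tests of Xist and the X-linked genes were set before their result was seen. Genes named here were chosen after their values were seen.

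Xist, the noncoding RNA that coats the inactive X chromosome, was among the most abundant changed transcripts. It fell from 2010 ± 609 to 743 ± 250 CPM (SD, n = 3 each), a log2 fold change of -1.43 (SE 0.26, edgeR adjusted p = 0.00232). A hypothesis was that lower Xist may go with a higher output of X-linked genes. The 386 tested X-linked protein-coding genes had a median log2 fold change of -0.055, at percentile 0.43 of 10000 sets of autosomal genes matched on expression (central range -0.041 to 0.059), so the test argues against it. Of these genes 20.7% fell and 10.1% rose, beside 19.2 and 11.9% of autosomal genes.

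Some of the steepest falls lay below the expression limit of the naming rule. Map7d3, a microtubule-associated protein gene, went from 10.1 ± 0.895 to 0.109 ± 0.0221 CPM, and Mgarp, which encodes a mitochondrial protein, from 6.45 ± 1.77 to 0.0137 ± 0.0237 CPM (edgeR adjusted p = 1.62e-07 and 3.89e-06). Celsr1, a planar polarity cadherin gene, went from 2.39 ± 0.286 to 0.0273 ± 0.0473 CPM.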
